A study of Mus musculus with 12 samples.

How the data were processed

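Bulk RNA-seq libraries of intestinal epithelial cells from mouse jejunum were analysed: Ctrl and Fzd5KO at day 1 and day 3, 3 libraries in each of 4 groups. RNA was purified with an RNeasy kit and libraries were made with a TruSeq Stranded Total RNA kit, per the labels' protocols. The submitters' processing notes name bcl2fastq 2.18, STAR 2.7.3a, RSEM without a version and the mouse genome build mm10, with no role or order for them. The annotation and whether strand was used in counting are not given in the sources used here. The authors deposited 1 table of TPM values, transcript abundances scaled to the same total in each library, for 55421 genes, 1 column for each of the 12 libraries, with 0 columns of any other sample. Of these genes 23594 were at 0 in every library.

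TPM scales each library to a fixed total and divides by transcript length, so depth was unknown. No interval for counting error or limit for a value of 0 could be given. A few abundant RNAs can shift all other TPM values, so other scalings were tried. Total RNA libraries keep small RNAs such as 7SL and 7SK (19.7 to 27.2% of the TPM) and mitochondrial genes (mt- symbols, 7.03 to 10.0%). The latter share leaves out the abundant Gm28437, Gm28661, Gm29216 and Gm10925. Whether these share reads with mt- genes was not tested. Identifiers were matched to GENCODE mouse release 21 (GRCm38, the same assembly as mm10), which gave symbols and coordinates counted from 1 for 55240. No match was found for 181, and 119 symbols were shared by more than 1 gene.

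Values were tested as log2(TPM + 1) with limma 3.58.1 in R 4.3.3, with a mean for each of the 4 groups, all 12 libraries sharing 1 estimate of the spread (8 residual degrees of freedom) and an intensity trend in the empirical Bayes step. Genes with at least 1 TPM in at least 3 libraries were tested (14510). Contrasts were Fzd5KO minus Ctrl at day 1, at day 3 and as the mean of both days, the difference between the days' effects (interaction), and day 3 minus day 1 within each genotype. P-values were adjusted by the Benjamini-Hochberg method over all tested genes within a contrast and called under 0.05. Of 35 gene lists, 33 had at least 4 tested members and were tested with camera at a preset correlation of 0.01, adjusted over the lists of a contrast. Each list was also tested with an estimated correlation and with fry. Member counts are given with adjustment over all tested genes and adjusted over the list alone. Fzd5 was also tested by exact permutation. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

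The groups, contrasts, lists, alternatives and the rule for named genes were chosen before the data were examined. The rule took the 10 largest rises and 10 largest falls on each day among called genes with at least 5 TPM in the higher group and no overlap between the groups. It took 5 in each direction for the interaction, without the overlap condition, and for each time contrast. Predicted and small RNA genes were left out of naming only. From each list described, up to 4 called members with the smallest p were eligible, and 15 genes were named whatever their result. Some genes that the rule named are not reported here. Mettl21a met the rule, while 2810408I11Rik, Ccnyl1 and Arntl were named after their values were seen. The comparison of day 3 calls with Ctrl day 1, the assignment of clock genes to opposite sides and the tests weighed in the closing section were also chosen after the data were seen. The ribosomal protein list first lost most large-subunit genes through a faulty symbol pattern. It was corrected to the rule fixed beforehand after its first results were seen, which gave 86 tested members.

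Alternatives were pseudocounts of 0.1 and 5, no filter, a filter of at least 5 TPM, quantile normalization, median-of-ratios scaling, and TPM rescaled without mitochondrial genes, predicted and small RNA genes and the 20 most abundant genes. Others were no trend, array weights, the replicate number as a block, only the libraries of the groups compared, a change of at least 1 on the log2 scale, and each library left out in turn. The procedure was tested on data simulated for the day 3 genotype comparison, with 200 of 14510 genes changed. It recovered 26% of genes changed by 0.25 (log2), 80% at 0.5, 94% at 1 and 100% at 2. Of its calls 3.23% were false. In the day 1 genotype contrast and the time contrast in the control, which held no simulated effect, limma called 0 genes. Camera called a list shifted by −0.5 and 0 of 32 others, but up to 24 in other splits of the real day 3 libraries.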

Results

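Gene expression was measured by bulk RNA-seq in intestinal epithelial cells from the jejunum of mice. Control samples (Ctrl) were compared with samples labelled as a knockout of Fzd5 (Fzd5KO), the gene for Frizzled 5, a cell-surface receptor for Wnt ligands. Samples of both genotypes carried a time point of day 1 or day 3, and the labels do not say from which event the days were counted. Each of the 4 groups held 3 libraries. The labels do not say that replicates came from separate animals, so p-values measure only the spread between these libraries, which may be technical. The values were TPM, so depth was unknown. Between 21506 and 24467 genes lay above 0 in a library, the highest number in Ctrl day 1 replicate 1. Of 55421 listed genes, 14510 reached 1 TPM in at least 3 libraries and were tested. Levels below are mean TPM ± SD of n = 3 libraries, and changes are on the log2(TPM + 1) scale ± SE, which understates the change of low genes.

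The groups separated in a principal component analysis of the log2 values. The first component held 41.05% of the variance and set Fzd5KO day 3 (mean score −41.8) against Ctrl day 3 (34.1), with Fzd5KO day 1 (−2.01) and Ctrl day 1 (9.76) between them. Ctrl day 1 replicate 1 stood apart from replicates 2 and 3 of its group on the third component (−34.5 against −13.9 and −8.55) and on the fourth (−19.02 against 21.7 and 19.5). Without it, 2927 genes were called at day 1, against 3622 with it. 7SL and 7SK RNA took 26.2 to 27.2% of the TPM in Fzd5KO day 1 and 22.9 to 25.7% in Ctrl day 1. At day 3 their share was 19.7 to 21.9% in Fzd5KO and 19.8 to 21.1% in Ctrl. The median gene lay below 0 in the knockout on both days (log2 change −0.14 on each). Quantile normalization moved that median by 0.14 at day 1 and 0.11 at day 3, and median-of-ratios scaling moved it by 0.15 and 0.13, which brought it near 0. Rescaling without the most abundant and mitochondrial genes put it at −0.048 at day 1 and, farther from 0, at −0.21 at day 3. For the mean of both days these shifts were 0.12 and 0.14. The median change from day 1 to day 3 was 0.11 in each genotype, and median-of-ratios scaling moved it by −0.11 in Ctrl and −0.12 in Fzd5KO. Quantile normalization moved the knockout's by −0.12. Rescaling moved the median of the knockout time course and that of the genotype by day difference by −0.17 each. Small changes are therefore relative to the scale chosen.

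Fzd5 itself (ENSMUSG00000045005, chromosome 1, 64730558 to 64737751 on the minus strand, mm10) was lower in the knockout on both days. Its level was 46.6 ± 2.94 TPM in Ctrl and 32.7 ± 0.694 TPM in Fzd5KO at day 1, and 64.8 ± 3.95 and 38.6 ± 0.969 TPM at day 3. The knockout kept 70.2% of the control level at day 1 and 59.5% at day 3. The log2 changes were −0.50 ± 0.055 (adjusted p = 0.000151) and −0.73 ± 0.055 (adjusted p = 4.42e-07). Every knockout library lay below every control library of its day. A two-sided exact permutation test gave p = 0.1 on each day, the smallest that 3 libraries against 3 allow, and p = 0.005 for both days with labels exchanged within days. The part of the gene that was removed is not given in the sources used here, so a transcript outside that part would still be measured. The lower level goes in the direction the labels give and does not measure how much of the intact gene was lost.

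Genes beside Fzd5 changed strongly and were singled out after their values were seen. Mettl21a, which encodes a methyltransferase-like protein (64606473 to 64617242, minus strand), rose from 2.32 ± 0.445 to 29.9 ± 0.359 TPM at day 1 (log2 change 3.23 ± 0.094, adjusted p = 3.7e-09) and from 2.64 ± 0.234 to 42.9 ± 2.76 TPM at day 3 (log2 change 3.59 ± 0.094). The non-coding transcript 2810408I11Rik (64679871 to 64690659, minus strand) rose from 4.26 ± 0.954 to 96.2 ± 5.46 TPM and from 3.11 ± 0.283 to 126 ± 6.49 TPM (log2 changes 4.22 ± 0.11 and 4.95 ± 0.11). Ccnyl1, on the plus strand (64690455 to 64725644), fell from 19.8 ± 1.05 to 8.66 ± 0.702 TPM and from 17.3 ± 2.69 to 11.1 ± 1.103 TPM. The annotated ends of 2810408I11Rik and Ccnyl1 overlap on opposite strands. Whether strand was used in counting is not given in the sources used here, so their values are uncertain. Within 1 Mb of Fzd5, 2 of the other 11 tested genes changed by more than 1 in the same direction on both days, against 45 of 14498 tested genes elsewhere.

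**Figure D1:**
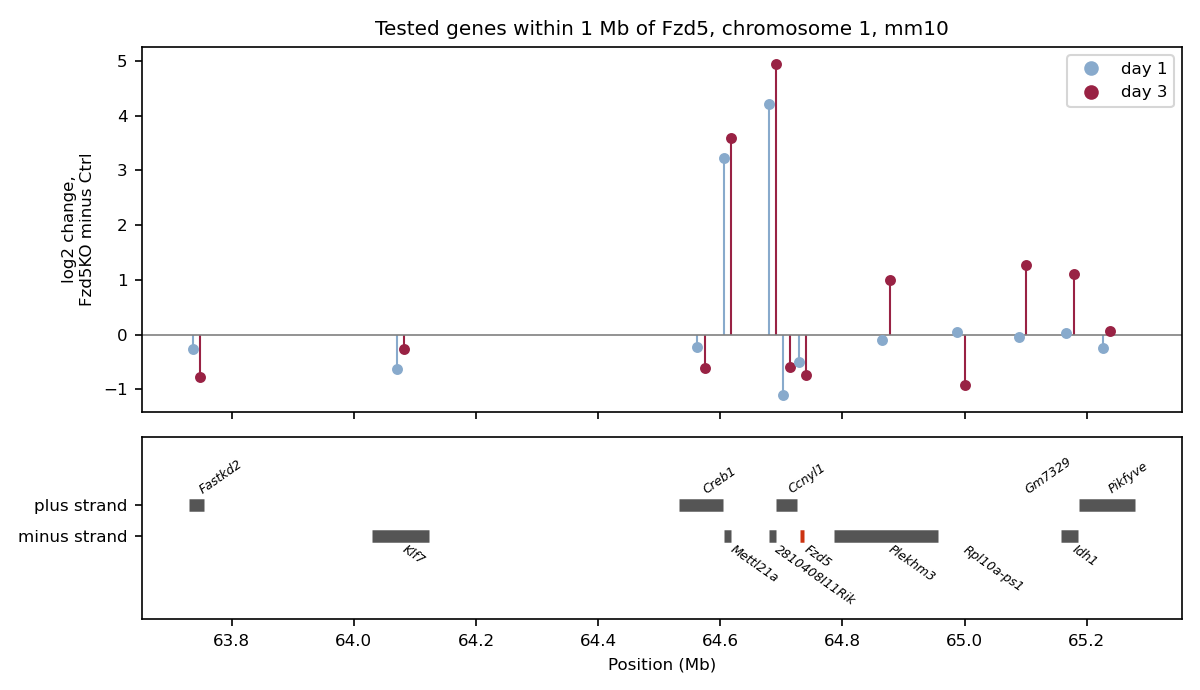
Log2 change of each tested gene within 1 Mb of Fzd5 on chromosome 1 (upper panel, day 1 in light blue and day 3 in dark red, Fzd5KO minus Ctrl) above the annotated genes by strand (lower panel, position in Mb, Fzd5 in red). Mettl21a and 2810408I11Rik on the minus strand rose by over 3 on the log2 scale on both days.

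At day 1 the knockout differed from control most clearly in markers of the crypt base. Olfm4, a secreted glycoprotein of crypt-base stem cells, fell from 284 ± 7.63 to 45.8 ± 0.270 TPM (log2 change −2.61 ± 0.041, adjusted p = 2.11e-11). Lgr5, the R-spondin receptor that marks these cells, fell from 4.31 ± 0.491 to 0.897 ± 0.197 TPM (log2 change −1.49 ± 0.13), and the stem cell transcription factor Ascl2 from 3.86 ± 0.323 to 1.38 ± 0.284 TPM (−1.03 ± 0.12). In the intestinal stem cell list, 17 of 19 tested members fell (17 adjusted over the list alone), mean log2 change −0.89 (camera adjusted p = 8.35e-15). This was the only list at day 1 whose call held with an estimated correlation (adjusted p = 0.0403). Among Wnt beta-catenin targets, 2 of 17 tested members rose and 9 fell (2 and 10 adjusted over the list alone), mean log2 change −0.44 (camera adjusted p = 0.0454, adjusted p = 0.345 with an estimated correlation). Axin2, a direct target that feeds back on the pathway, fell from 36.5 ± 0.615 to 20.5 ± 2.004 TPM (log2 change −0.80 ± 0.082), and Tnfrsf19 fell by 1.31. This list also holds Lgr5 and Ascl2, so it repeats part of the stem cell result. Its call was also lost with a pseudocount of 0.1 (adjusted p = 0.0662), a stricter filter (0.291), array weights (0.0528) or a fit of the day 1 libraries alone (0.0877). It was lost without Ctrl day 1 replicate 2 (0.067) or Ctrl day 3 replicate 1 (0.0642), 2 (0.0519) or 3 (0.0629). In the Wnt receptor list, without Fzd5, 8 of 11 tested members fell (9 adjusted over the list alone). Its mean log2 change was −0.45 (camera adjusted p = 0.0013, adjusted p = 0.133 with an estimated correlation). It holds the R-spondin receptor Lgr5 (−1.49), Lgr4 (−0.44) and Lrp6 (−0.35).

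Goblet cell, enteroendocrine and cell cycle genes were also lower at day 1. In the goblet cell list, 19 of 20 tested members fell (19 adjusted over the list alone), mean log2 change −0.56 (camera adjusted p = 2.94e-13, adjusted p = 0.133 with an estimated correlation). Muc2, the main secreted mucin, fell from 2568 ± 91.6 to 1492 ± 45.2 TPM (log2 change −0.78 ± 0.045), Fcgbp by 0.91 and Zg16 by 0.88. In the enteroendocrine list, 11 of 22 tested members fell (13 adjusted over the list alone), mean log2 change −0.36 (camera adjusted p = 0.00373, adjusted p = 0.133 with an estimated correlation), with Chgb at −0.54 and Chga, the granule protein chromogranin A, at −0.43 ± 0.050. Of S phase genes, 13 of 26 tested members fell (14 adjusted over the list alone), mean log2 change −0.23 (camera adjusted p = 0.0117, adjusted p = 0.22 with an estimated correlation). Of G2 and M phase genes, 15 of 26 tested members fell (18 adjusted over the list alone), mean log2 change −0.25 (camera adjusted p = 0.00553, adjusted p = 0.228 with an estimated correlation). The proliferation marker Mki67 fell from 53.2 ± 1.29 to 42.7 ± 0.146 TPM (log2 change −0.31 ± 0.047) and the replication helicase subunit Mcm7 by 0.33. In the Notch list, 8 of 12 tested members fell (9 adjusted over the list alone), mean log2 change −0.34 (camera adjusted p = 0.0106, adjusted p = 0.22 with an estimated correlation), with Notch1 at −0.84.

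Camera did not call the Paneth and tuft cell lists at day 1, while fry called both as lower (adjusted p = 0.00431 and 0.00179). In the Paneth cell list, 1 of 18 tested members rose and 9 fell (1 and 10 adjusted over the list alone), mean log2 change −0.28 (camera adjusted p = 0.108). That list was called without Fzd5KO day 1 replicate 3 (adjusted p = 0.0473) or without Ctrl day 1 replicate 3 (0.0412), with quantile normalization (0.0177), with the filter removed (0.00349) and in a fit of the day 1 libraries alone (0.0486). The lysozyme gene Lyz1 was at 3059.9 ± 139 and 2560.2 ± 43.8 TPM (log2 change −0.26 ± 0.040, adjusted p = 0.00134), a call lost with quantile normalization (0.357) and median-of-ratios scaling (0.108). Ang4 fell by 0.37 and Defa31 by 2.42, from 1992 ± 623 to 392 ± 193 TPM. The Defa genes are near-identical copies between which reads can be split, so single members are uncertain. In the tuft cell list, 3 of 15 tested members fell (3 adjusted over the list alone), mean log2 change −0.25 (camera adjusted p = 0.794), and its direction against the other genes turned without Ctrl day 1 replicate 1 (adjusted p = 0.865). Dclk1 stood at 6.33 ± 0.914 and 6.12 ± 0.846 TPM (log2 change −0.039 ± 0.19, adjusted p = 0.897), and its sign turned with each other scaling (0.12, 0.11 and 0.055). It also turned without Fzd5KO day 1 replicate 1 (0.0079) or 2 (0.0090) and without Ctrl day 1 replicate 2 (0.045).

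Absorptive enterocyte genes went both ways at day 1. In the enterocyte list, 6 of 27 tested members rose and 15 fell (6 and 15 adjusted over the list alone), mean log2 change −0.14 (camera adjusted p = 0.211), and the mean turned to 0.036 with median-of-ratios scaling. The list was called with the filter removed (adjusted p = 0.00258). Cubn, the cobalamin receptor cubilin, fell by 0.99, while the lipid carriers Apoa4 and Fabp1 rose by 0.57 and 0.42. Sis, the disaccharidase sucrase-isomaltase, was at 2086 ± 36.3 and 1551 ± 23.3 TPM (log2 change −0.43 ± 0.030), a call lost with quantile normalization (adjusted p = 0.283). Alpi, intestinal alkaline phosphatase, had a log2 change of −0.037 ± 0.040 (adjusted p = 0.523), which turned to 0.14 with median-of-ratios scaling (adjusted p = 0.00701) and 0.068 with the rescaled values. In the antimicrobial list, 4 of 12 tested members rose and 3 fell (4 and 4 adjusted over the list alone), mean log2 change 0.052 (camera adjusted p = 0.0143, adjusted p = 0.333 with an estimated correlation), with a median of −0.0039 below 0, and the call was lost with quantile normalization (0.069). Reg3b rose by 0.55 and Il18 by 0.48, and Pigr, which carries IgA across the epithelium, fell by 0.41. Among p53 targets, 2 of 22 tested members rose and 1 fell (2 and 1 adjusted over the list alone), mean log2 change 0.081 (camera adjusted p = 2e-06, adjusted p = 0.0796 with an estimated correlation). Ccng1 rose by 0.37, and Cdkn1a, the cell cycle inhibitor p21, had a log2 change of 0.10 ± 0.055 (adjusted p = 0.198) that passed with quantile normalization (0.00649), median-of-ratios scaling (0.00136) and the rescaled values (0.0106). Lists called as higher with means near 0 passed because camera compares their members with the other genes, whose median was −0.14.

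Immune, stress and abundance lists gave mixed results at day 1. In the MHC class II list, 6 of 8 tested members fell (6 adjusted over the list alone), mean log2 change −0.36 (camera adjusted p = 0.0117, adjusted p = 0.26 with an estimated correlation), with H2-Aa at −0.76 and H2-Ab1 at −0.60. In the interferon list, 2 of 23 tested members rose and 11 fell (2 and 11 adjusted over the list alone), mean log2 change −0.22 (camera adjusted p = 0.211), and it was called with the filter removed (0.00386). Among immediate early genes, 3 of 16 tested members rose and 1 fell (3 and 1 adjusted over the list alone), mean log2 change 0.093 (camera adjusted p = 0.000117, adjusted p = 0.22 with an estimated correlation), with Fos at 0.31 and Hspa1b at 0.69. Of BMP and TGF-beta targets, 1 of 10 tested members rose and 6 fell (1 and 8 adjusted over the list alone), mean log2 change −0.23 (camera adjusted p = 0.292). Among unfolded protein response genes, 6 of 21 tested members fell (6 adjusted over the list alone), mean log2 change −0.11 (camera adjusted p = 0.728), and its mean turned to 0.014 with quantile normalization and 0.055 with median-of-ratios scaling. Its direction against other genes also turned without Fzd5KO day 1 replicate 3 (adjusted p = 0.972). In the cholesterol list 5 of 20 tested members fell (1 rose and 7 fell adjusted over the list alone), with a mean of −0.10 (camera adjusted p = 0.697). It turned to 0.021 with quantile normalization (0.481) and to 0.065 with median-of-ratios scaling, where camera called it as higher (0.045). In the fetal-like list, 1 of 12 tested members rose and 1 fell (1 and 1 adjusted over the list alone), mean log2 change −0.026 (camera adjusted p = 0.0524). Its median was 0.0076 and its direction against other genes was up, and the mean turned to 0.13, 0.11 and 0.049 with the other scalings. That list was called without Fzd5KO day 1 replicate 3 (adjusted p = 0.0346), Fzd5KO day 3 replicate 1 (0.0466), 2 (0.0441) or 3 (0.0443), or Ctrl day 1 replicate 1 (0.0276), with a stricter filter (0.0493) and in a fit of the day 1 libraries alone (0.03). Ly6a (log2 change −0.29 ± 0.13) and Clu (−0.24 ± 0.10) did not pass, and Clu passed without Ctrl day 1 replicate 3 (log2 change −0.34, adjusted p = 0.0329).

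In the ribosomal protein list 5 of 86 tested members rose and 1 fell at day 1 by limma, 0 adjusted over the list alone, with 12 higher and 4 lower at an unadjusted p under 0.05. Its mean log2 change was 0.016 (camera adjusted p = 4.71e-10, and adjusted p = 0.22 with an estimated correlation). The list includes 8 S6 kinase genes, which share the symbol prefix and are not ribosomal proteins. Of the mitochondrially encoded list 0 of 15 tested members were called by limma, with 2 higher and 1 lower at an unadjusted p under 0.05. Its mean was 0.013, turning to −0.0041 with quantile normalization (camera adjusted p = 2.19e-05, adjusted p = 0.22 with an estimated correlation, and 0.411 with quantile normalization). In the circadian clock list, 1 of 17 tested members rose and 4 fell (1 and 4 adjusted over the list alone), mean log2 change −0.11 (camera adjusted p = 0.477), with a direction up against other genes and means of 0.037 and 0.047 with quantile normalization and median-of-ratios scaling. Nr1d1, which encodes the clock repressor REV-ERB alpha, fell by 0.73.

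Camera called none of the 6 tested lists of other cell types at day 1. Fry called the T cell (adjusted p = 0.00556), B and plasma cell (0.00129), fibroblast (0.00304) and erythroid lists (0.00212) as lower. Of T cell and intraepithelial lymphocyte markers, 1 of 15 tested members rose and 6 fell (1 and 6 adjusted over the list alone), mean log2 change −0.31 (camera adjusted p = 0.222), with calls under quantile normalization (0.0344), median-of-ratios scaling (0.0129) and no filter (0.00597). In the B and plasma cell list, 3 of 11 tested members fell (6 adjusted over the list alone), mean log2 change −0.42 (camera adjusted p = 0.0955), with calls under quantile normalization (0.00691), median-of-ratios scaling (0.0011), rescaling (0.00488) and no filter (0.00386). In the myeloid list, 1 of 13 tested members fell (1 adjusted over the list alone), mean log2 change −0.10 (camera adjusted p = 0.222), with a direction up against other genes and a mean of 0.056 with quantile normalization. In the fibroblast and smooth muscle list, 2 of 10 tested members fell (2 adjusted over the list alone), mean log2 change −0.30 (camera adjusted p = 0.62), called with median-of-ratios scaling (0.0395) and no filter (0.0281). Of the endothelial list 0 of 4 tested members were called by limma, 0 at an unadjusted p under 0.05, with a mean of −0.15 (0.0098 with quantile normalization) and a direction up against other genes (camera adjusted p = 0.728), which turned without Fzd5KO day 1 replicate 3 (0.972). In the erythroid list, 3 of 5 tested members fell (4 adjusted over the list alone), mean log2 change −0.59 (camera adjusted p = 0.0519), with calls under quantile normalization (0.00691), median-of-ratios scaling (0.00462), rescaling (0.00889) and no filter (0.00386). It was also called without Fzd5KO day 1 replicate 3 (0.0166), Fzd5KO day 3 replicate 1 (0.0391) or 3 (0.0488), or Ctrl day 1 replicate 1 (0.0276) or 3 (0.0285). The pancreatic acinar and enteric neuron lists had 2 and 1 tested members and were too small to test.

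Among the largest rises at day 1 after Mettl21a, Nt5e, which makes extracellular adenosine, rose from 16.6 ± 0.431 to 37.8 ± 0.573 TPM (log2 change 1.14 ± 0.044), the nucleoside transporter Slc28a2 from 75.1 ± 0.414 to 158 ± 1.57 TPM (1.06 ± 0.034) and adenosine deaminase Ada from 118 ± 11.05 to 230.1 ± 4.43 TPM (0.96 ± 0.062). The mast cell protease Mcpt1 rose by 1.41, the bile-acid-responsive hormone Fgf15 by 1.33, Scgb2b17 by 0.99, Ankrd37 by 0.94, Paqr7 by 0.92 and Xcl1 by 0.90. The metallothioneins Mt2 and Mt1 fell from 75.1 ± 2.12 to 17.7 ± 2.08 TPM and from 232 ± 15.5 to 97.6 ± 3.08 TPM. Afp fell by 1.33, Rims2 by 1.32, Esrrg by 1.29, the RNA-binding protein Msi1 by 1.28 and Igfbp4 by 1.27. Hist1h2br, one of a family of near-identical histone genes and therefore uncertain, had a log2 change of −1.83 ± 0.55 (adjusted p = 0.0336). Its call was lost without Fzd5KO day 1 replicate 1 (adjusted p = 0.0947), Ctrl day 1 replicate 1 (0.0743) or 2 (0.108), and with no filter (0.0887), quantile normalization (0.076), median-of-ratios scaling (0.0677) or the day 1 libraries alone (0.0603).

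Over all tested genes, limma with Benjamini-Hochberg adjustment called 3622 at day 1, 309 higher and 3313 lower, and 71 of them changed by at least 1. The share of higher genes depended on the scale: 8.53% as deposited, 48.1% of 1771 calls with quantile normalization, 62.5% of 2216 with median-of-ratios scaling and 35.8% of 1925 with rescaling. Without Ctrl day 1 replicate 2 the count was 2229. Of the 33 lists tested, camera called 16, with 7 higher and 9 lower, 1 held with an estimated correlation, and fry, which tests whether members move on balance in 1 direction and does not compare with other genes, called 24. Fry, unlike camera, also called as lower the enterocyte (adjusted p = 0.00192), BMP (0.00161), unfolded protein (0.00575), interferon (0.000383), cholesterol (0.0118), proximal (0.00218) and circadian lists (0.00949). In 43.4% of genes the groups did not overlap, against 10% by chance.

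**Figure D2:**
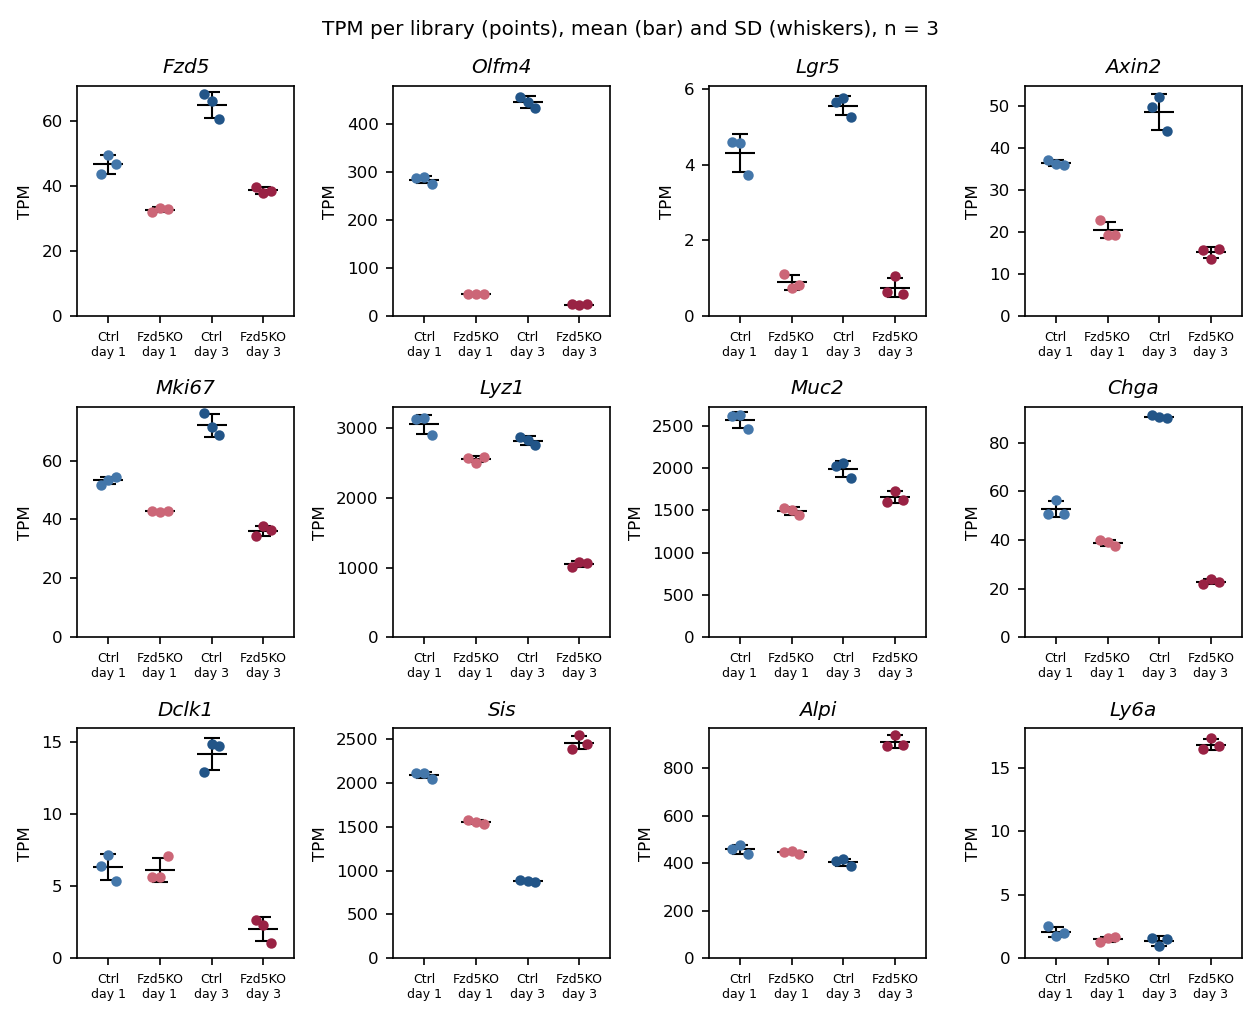
TPM of Fzd5 and markers of stem cells, proliferation, Paneth, goblet, enteroendocrine and tuft cells, enterocytes and Ly6a in the 4 groups (points, libraries; bars, mean; whiskers, SD; n = 3; each axis starts at 0). Olfm4 had means of 45.8 ± 0.270 TPM in Fzd5KO day 1 and 24.5 ± 1.33 TPM in Fzd5KO day 3, below every control library.

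At day 3 the knockout had lower stem cell, Paneth, enteroendocrine, tuft and proliferation markers and higher enterocyte, interferon and antigen presentation genes. The control group of this day stood apart from the other 3 groups in some gene sets. The circadian gene Nr1d1 was at 0.737 ± 0.231 TPM in Ctrl day 3, against 21.2 ± 0.462 in Ctrl day 1, 12.4 ± 0.287 in Fzd5KO day 1 and 17.9 ± 0.673 in Fzd5KO day 3. Dbp, another clock output, was at 2.86 ± 0.504 TPM there, against 35.2 ± 0.526, 29.1 ± 0.782 and 22.99 ± 2.09. In the T cell list 14 of 15 members fell from Ctrl day 1 to Ctrl day 3, and Gzma, a granzyme of cytotoxic lymphocytes, fell from 106 ± 5.63 to 22.3 ± 1.45 TPM. Each list below is therefore given also as the mean change of Fzd5KO day 3 against Ctrl day 1, a comparison chosen after the data were seen that mixes genotype with time.

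Stem cell and Wnt target genes were lower at day 3. Olfm4 fell from 446 ± 11.8 to 24.5 ± 1.33 TPM (log2 change −4.13 ± 0.041, adjusted p = 1.32e-13), Lgr5 from 5.56 ± 0.253 to 0.760 ± 0.261 TPM (−1.91 ± 0.13), Ascl2 from 6.07 ± 0.178 to 0.423 ± 0.163 TPM (−2.32 ± 0.12) and Axin2 from 48.6 ± 4.21 to 15.2 ± 1.27 TPM (−1.62 ± 0.082). In the stem cell list, 18 of 19 tested members fell (18 adjusted over the list alone), mean log2 change −1.71 (camera adjusted p = 5.89e-10), and −1.22 against Ctrl day 1. In the Wnt target list, 2 of 17 tested members rose and 14 fell (2 and 14 adjusted over the list alone), mean log2 change −0.85 (camera adjusted p = 0.0011, adjusted p = 0.0945 with an estimated correlation), and −0.63 against Ctrl day 1. In the Wnt receptor list, 1 of 11 tested members rose and 8 fell (1 and 8 adjusted over the list alone), mean log2 change −0.61 (camera adjusted p = 0.0147, adjusted p = 0.123 with an estimated correlation), and −0.43 against Ctrl day 1. Its call was lost with a stricter filter (0.154), and Lgr5, Ror2 and Fzd1 fell by 1.91, 1.22 and 0.97. In the Notch list, 1 of 12 tested members rose and 9 fell (1 and 9 adjusted over the list alone), mean log2 change −0.67 (camera adjusted p = 0.00452, adjusted p = 0.0942 with an estimated correlation), and −0.30 against Ctrl day 1, with Notch1 at −1.72 and Nrarp at −1.14.

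Cell cycle genes fell nearly throughout both lists. For S phase genes, 25 of 26 tested members fell (26 adjusted over the list alone), mean log2 change −0.85 (camera adjusted p = 3.49e-08), and −0.61 against Ctrl day 1. For G2 and M phase genes, 26 of 26 tested members fell (26 adjusted over the list alone), mean log2 change −0.92 (camera adjusted p = 1.35e-09), and −0.55 against Ctrl day 1. Mki67 fell from 71.96 ± 3.83 to 36.2 ± 1.71 TPM (log2 change −0.97 ± 0.047), the DNA topoisomerase Top2a by 1.05, Mcm7 by 1.20 and Tyms, which makes thymidylate, by 1.16. In the ribosomal protein list, 2 of 86 tested members rose and 77 fell (3 and 77 adjusted over the list alone), mean log2 change −0.56 (camera adjusted p = 2.73e-17, adjusted p = 0.0566 with an estimated correlation), and −0.25 against Ctrl day 1. Rps3a1 fell by 0.73 and Rpl4 by 0.69, while among the 8 S6 kinase genes in the list 2 rose and 2 fell. Of mitochondrially encoded genes, 10 of 15 tested members fell (10 adjusted over the list alone), mean log2 change −0.36 (camera adjusted p = 0.0175, adjusted p = 0.365 with an estimated correlation), and −0.46 against Ctrl day 1, with mt-Nd4 at −0.63.

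Secretory cell markers were lower at day 3 in all 4 lineages. In the Paneth cell list, 18 of 18 tested members fell (18 adjusted over the list alone), mean log2 change −1.58 (camera adjusted p = 1.11e-10, adjusted p = 0.0522 with an estimated correlation), and −1.86 against Ctrl day 1. Lyz1 fell from 2824 ± 61.3 to 1052 ± 40.1 TPM (log2 change −1.42 ± 0.040), and the alpha-defensin Defa30, uncertain as noted above for its family, from 2392 ± 118 to 569.8 ± 23.8 TPM. In the goblet cell list, 19 of 20 tested members fell (19 adjusted over the list alone), mean log2 change −0.73 (camera adjusted p = 4.79e-07, adjusted p = 0.113 with an estimated correlation), and −0.62 against Ctrl day 1. Muc2 fell from 1990.5 ± 90.9 to 1654 ± 70.4 TPM (log2 change −0.27 ± 0.045), Ccl6 by 1.26 and Spink4 by 1.15. In the enteroendocrine list, 20 of 22 tested members fell (20 adjusted over the list alone), mean log2 change −1.12 (camera adjusted p = 8.95e-07), and −0.77 against Ctrl day 1, with Chga falling from 90.6 ± 0.536 to 22.9 ± 1.12 TPM and the incretin gene Gip by 1.78. In the tuft cell list, 13 of 15 tested members fell (13 adjusted over the list alone), mean log2 change −1.24 (camera adjusted p = 0.000123), and −0.72 against Ctrl day 1. Dclk1 fell from 14.2 ± 1.097 to 2.003 ± 0.832 TPM (log2 change −2.38 ± 0.19).

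Enterocyte genes rose at day 3. In the enterocyte list, 25 of 27 tested members rose and 1 fell (25 and 1 adjusted over the list alone), mean log2 change 1.07 (camera adjusted p = 6.85e-18, adjusted p = 0.0815 with an estimated correlation), and 0.50 against Ctrl day 1. Sis was 877 ± 13.6 TPM in Ctrl and 2457 ± 76.7 TPM in Fzd5KO (log2 change 1.48 ± 0.030), Alpi rose from 404 ± 15.96 to 911 ± 26.9 TPM (1.17 ± 0.040), the peptide transporter Slc15a1 by 1.76, the glucose transporters Slc2a2 by 1.82 and Slc5a1 by 1.62. In the cholesterol list, 19 of 20 tested members rose (19 adjusted over the list alone), mean log2 change 0.59 (camera adjusted p = 1.35e-09), and 0.54 against Ctrl day 1, with Sqle at 1.09 and Hmgcs1 at 0.84. In the unfolded protein response list, 15 of 21 tested members rose and 2 fell (16 and 2 adjusted over the list alone), mean log2 change 0.30 (camera adjusted p = 0.000123, adjusted p = 0.0899 with an estimated correlation), and 0.25 against Ctrl day 1, with Dnajb9 at 0.84 and Trib3 at 1.70. In the p53 target list, 12 of 22 tested members rose and 1 fell (12 and 1 adjusted over the list alone), mean log2 change 0.29 (camera adjusted p = 0.000323, adjusted p = 0.0566 with an estimated correlation), and 0.22 against Ctrl day 1. Cdkn1a rose from 30.5 ± 1.32 to 62.5 ± 2.36 TPM (log2 change 1.01 ± 0.055).

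**Figure D3:**
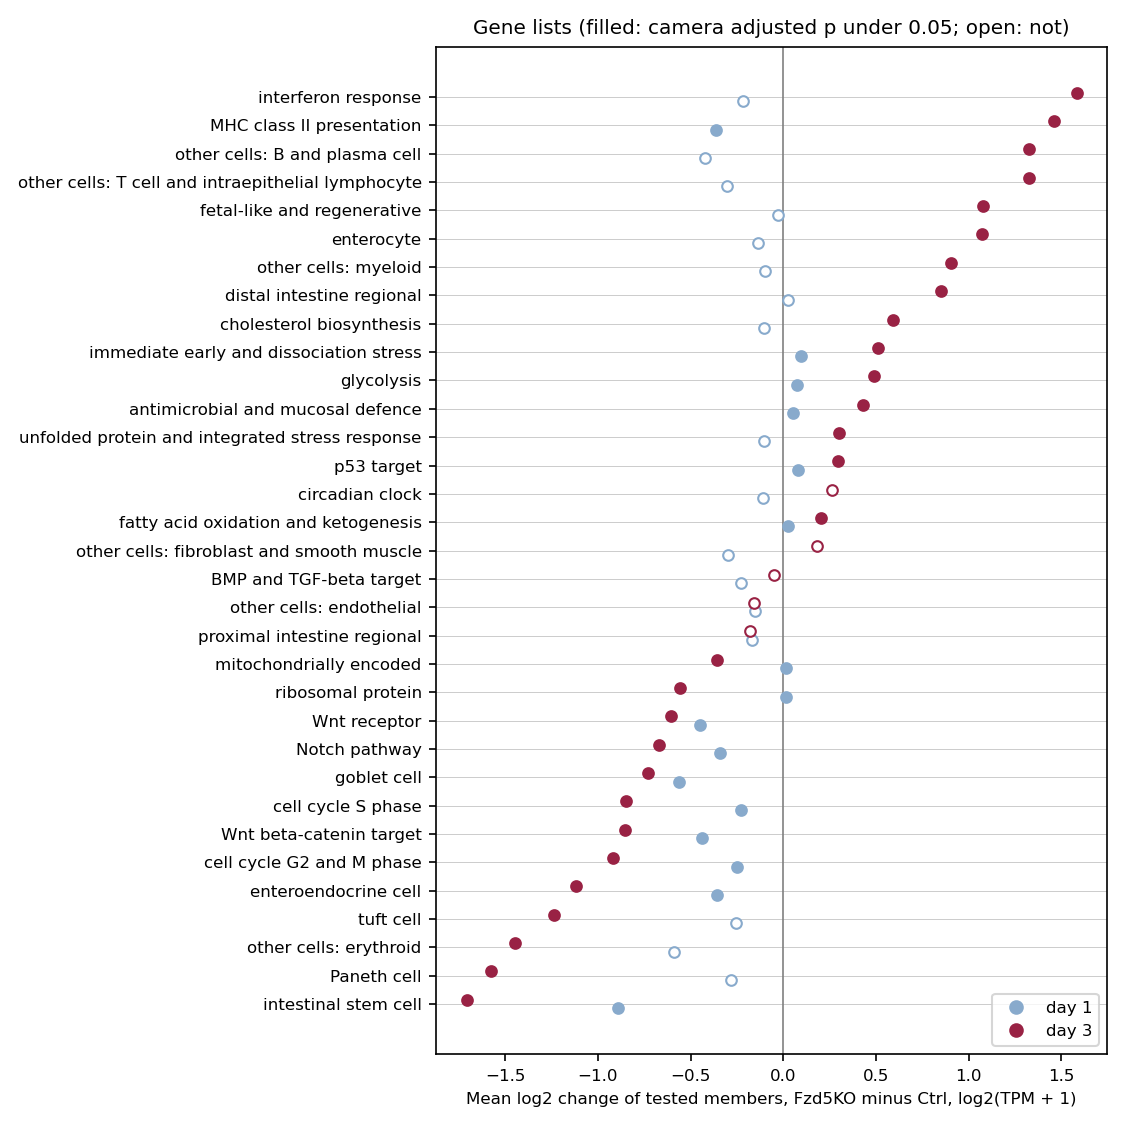
Mean log2 change of the tested members of each list, Fzd5KO minus Ctrl (horizontal axis, log2(TPM + 1)), at day 1 (light blue) and day 3 (dark red), with filled points for a camera adjusted p under 0.05. At day 3 the interferon list had the highest mean (1.58) and the stem cell list the lowest (−1.71).

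Interferon-stimulated and antigen presentation genes rose at day 3. In the interferon list, 23 of 23 tested members rose (23 adjusted over the list alone), mean log2 change 1.58 (camera adjusted p = 3.68e-16), and 1.11 against Ctrl day 1. Ifi44 rose from 1.46 ± 0.195 to 27.4 ± 1.63 TPM (log2 change 3.53 ± 0.093), Tap1, part of the peptide transporter for MHC class I, by 1.66, Oasl2 by 1.88 and the nucleic acid sensor Zbp1 by 2.22. In the MHC class II list, 8 of 8 tested members rose (8 adjusted over the list alone), mean log2 change 1.46 (camera adjusted p = 6.64e-07), and 0.61 against Ctrl day 1, with the invariant chain Cd74 at 1.94 and H2-Ab1 at 1.79. In the antimicrobial list, 8 of 12 tested members rose and 3 fell (8 and 3 adjusted over the list alone), mean log2 change 0.43 (camera adjusted p = 0.01, adjusted p = 0.208 with an estimated correlation), and 0.77 against Ctrl day 1. Its members moved apart: the hydrogen peroxide producing Duox2 and its partner Duoxa2 rose by 1.37 and 1.80, and the lectin Reg3a and the chemokine Ccl28 fell by 1.44 and 1.39. In the fetal-like list, 9 of 12 tested members rose and 1 fell (9 and 1 adjusted over the list alone), mean log2 change 1.08 (camera adjusted p = 0.000123), and 0.74 against Ctrl day 1. Ly6a, also called Sca-1, rose from 1.36 ± 0.361 to 16.8 ± 0.444 TPM (log2 change 2.93 ± 0.13), the EGF-family ligand Areg by 2.54, the alarmin Il33 by 2.44 and Clu by 0.39. Of immediate early genes, 9 of 16 tested members rose and 3 fell (9 and 3 adjusted over the list alone), mean log2 change 0.51 (camera adjusted p = 0.00118, adjusted p = 0.189 with an estimated correlation), and 0.32 against Ctrl day 1, with Fos at 1.14 and Zfp36 at 0.95.

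Markers of immune cells were higher in the knockout at day 3. In the list of T cells and intraepithelial lymphocytes, 15 of 15 tested members rose (15 adjusted over the list alone), mean log2 change 1.32 (camera adjusted p = 1.67e-07, adjusted p = 0.0572 with an estimated correlation), but −0.082 against Ctrl day 1. Gzma stood at 22.3 ± 1.45 TPM in Ctrl and 95.2 ± 4.24 TPM in Fzd5KO. In the B and plasma cell list, 10 of 11 tested members rose (10 adjusted over the list alone), mean log2 change 1.33 (camera adjusted p = 8.46e-06), and 1.22 against Ctrl day 1, with Igkc at 1.89 and Jchain at 1.59. In the myeloid list, 11 of 13 tested members rose (11 adjusted over the list alone), mean log2 change 0.90 (camera adjusted p = 0.000115), and 0.69 against Ctrl day 1, with Lyz2 at 1.16. In the fibroblast and smooth muscle list 1 of 10 tested members rose by limma (0 adjusted over the list alone, 1 at an unadjusted p under 0.05), mean log2 change 0.18 (camera adjusted p = 0.214), and 0.12 against Ctrl day 1. In the endothelial list, 2 of 4 tested members rose and 2 fell (2 and 2 adjusted over the list alone), mean log2 change −0.16 (camera adjusted p = 0.828), with a direction up against other genes that turned with median-of-ratios scaling, a mean of 0.015 with quantile normalization, and −0.067 against Ctrl day 1. In the erythroid list, 5 of 5 tested members fell (5 adjusted over the list alone), mean log2 change −1.45 (camera adjusted p = 0.00753, adjusted p = 0.146 with an estimated correlation), and −0.54 against Ctrl day 1, with Hbb-bs at −1.76. In the list of BMP and TGF-beta targets, 3 of 10 tested members rose and 3 fell (3 and 3 adjusted over the list alone), mean log2 change −0.053 (camera adjusted p = 0.595), with a median of 0.037 means of 0.033 and 0.081 with quantile normalization and median-of-ratios scaling, and −0.064 against Ctrl day 1.

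Circadian clock genes split by direction at day 3. Across the clock list, 7 of 17 tested members rose and 7 fell (7 and 7 adjusted over the list alone), mean log2 change 0.26 (camera adjusted p = 0.471), with a median of −0.053 and −0.030 against Ctrl day 1. Nr1d1 and Dbp rose by 3.46 and 2.64. Arntl, the gene of the clock activator BMAL1 and named here after its values were seen, was 24.9 ± 0.819 TPM in Ctrl day 3 against 7.24 ± 0.636 in Ctrl day 1, 7.04 ± 0.231 in Fzd5KO day 1 and 6.903 ± 0.562 in Fzd5KO day 3. From Ctrl day 1 to Ctrl day 3, 5 of the 6 listed genes on the side of Arntl rose, while of the 11 on the side of Nr1d1 7 fell and 3 rose.

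**Figure D4:**
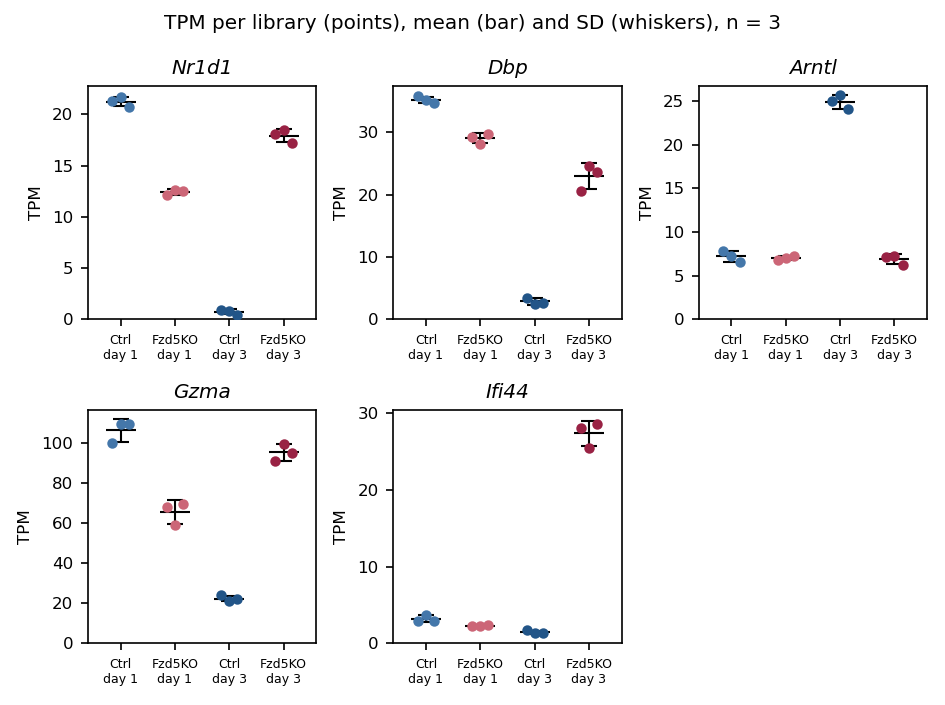
TPM of the clock genes Nr1d1, Dbp and Arntl, the lymphocyte gene Gzma and the interferon-stimulated gene Ifi44 in the 4 groups (points, libraries; bars, mean; whiskers, SD; n = 3; each axis starts at 0). Nr1d1, Dbp and Gzma were lowest in Ctrl day 3 and Arntl highest there, while Ifi44 was highest in Fzd5KO day 3.

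Other genes with the largest changes at day 3 included Ubd, an interferon-inducible ubiquitin-like modifier, which rose from 0.567 ± 0.186 to 83.2 ± 3.29 TPM (log2 change 5.75 ± 0.14). Ada rose from 70.9 ± 4.097 to 804 ± 14.3 TPM (3.49 ± 0.062), the cornified envelope gene Sprr2a2 from 183 ± 12.8 to 1535 ± 58.2 TPM and its near-identical copy Sprr2a3 by 3.03, both uncertain for that reason. The immunoglobulin segment Igkv6-15 rose by 2.89. The carboxylesterase gene Ces1d fell from 60.2 ± 0.347 to 1.18 ± 0.443 TPM, and Reg1 from 52.6 ± 5.43 to 3.89 ± 0.553 TPM. Ces1d was at 14.4 ± 1.66 TPM in Ctrl day 1. Afp fell by 2.88, the stem cell list member Gkn3 by 2.53, Sorbs2 by 2.45, the cysteine dioxygenase gene Cdo1 by 2.42 and colipase, Clps, by 2.41. Hist1h2bq, of the near-identical histone family, had a log2 change of −2.54 ± 0.76 (adjusted p = 0.0129), and its call was lost without Fzd5KO day 3 replicate 2 (−1.70, adjusted p = 0.051). AY036118 passed the test (−9.64 ± 2.56) with levels of 10883 ± 14251 TPM in Ctrl and 63.7 ± 110.4 TPM in Fzd5KO, an SD above the mean in both groups.

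At day 3, limma called 9113 genes, 3529 higher and 5584 lower, and 1264 changed by at least 1. Higher genes made up 38.7% of calls as deposited and 52.6% of 8819 with median-of-ratios scaling (4637 higher and 4182 lower). Camera called 28 of 33 lists, 15 higher and 13 lower, 13 held with an estimated correlation, and fry called 31, with the proximal list lower (adjusted p = 0.000265) and the circadian (0.000149) and fibroblast lists (0.028) higher. Of the 9113 genes, 5933 were also called in the same direction against Ctrl day 1, and 134 in the opposite one. That kept 80.8% of the higher genes (2851) and 55.2% of the lower genes (3082), against 887.7 and 1304 for independent lists of these sizes. Both comparisons use the same knockout libraries: log2 changes had the same sign in 81.9% of genes (66.6% simulated with no effect), with r = 0.806 across genes (0.489 simulated) and a covariance of 0.252 (0.0221 simulated). Genes are not independent replicates, and part of the excess may come from the shared libraries. Groups did not overlap in 66.5% of genes, against 10% by chance.

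The mean of the genotype changes over both days repeated the lower crypt lists. For stem cell genes, 18 of 19 tested members fell (18 adjusted over the list alone), mean log2 change −1.30 (camera adjusted p = 6.66e-11). Across the mean, of S phase genes 25 of 26 tested members fell (26 adjusted over the list alone), mean log2 change −0.54 (camera adjusted p = 1.25e-07). Of G2 and M phase genes on this mean, 26 of 26 tested members fell (26 adjusted over the list alone), mean log2 change −0.58 (camera adjusted p = 4.65e-09). In the Paneth list, 18 of 18 tested members fell (18 adjusted over the list alone), mean log2 change −0.93 (camera adjusted p = 3.71e-10, adjusted p = 0.0581 with an estimated correlation). Limma called 8543 genes, 2548 higher and 5995 lower. Higher genes made up 29.8% as deposited, 49.0% with quantile normalization and 55.5% with median-of-ratios scaling (4316 higher and 3467 lower). Camera called 27 lists, 13 with an estimated correlation. Between the days, as deposited, 1712 genes were lower on both (1275 for independent lists) and 203 higher on both (75.15), while 816 lower at day 1 were higher at day 3 (805.8) and 53 higher at day 1 were lower at day 3 (118.9). The 1712 depends on the scale, since 920 genes in all were lower at day 1 with quantile normalization, 830 with median-of-ratios scaling and 1235 with rescaling. The log2 changes of the days correlated weakly across genes (Pearson r = 0.195, Spearman rho = 0.218).

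The difference between the days in the genotype effect was tested as an interaction, day 3 minus day 1. It was positive for enterocyte genes, where 27 of 27 tested members rose (27 adjusted over the list alone), mean log2 change 1.21 (camera adjusted p = 2.42e-21, adjusted p = 0.0717 with an estimated correlation). Interferon genes were also positive, where 23 of 23 tested members rose (23 adjusted over the list alone), mean log2 change 1.80 (camera adjusted p = 8.63e-16). The interaction was above 0 in Ubd (5.90 ± 0.20), Nr1d1 (4.18 ± 0.12), Ifi44 (3.88 ± 0.13), Ly6a (3.22 ± 0.18) and Igkv6-15, listed at 0 in Fzd5KO day 1. For MHC class II genes, 8 of 8 tested members rose (8 adjusted over the list alone), mean log2 change 1.82 (camera adjusted p = 7.72e-07). For the T cell list, 14 of 15 tested members rose (14 adjusted over the list alone), mean log2 change 1.63 (camera adjusted p = 9.76e-07, adjusted p = 0.0791 with an estimated correlation). It was negative for Paneth genes, where 17 of 18 tested members fell (17 adjusted over the list alone), mean log2 change −1.29 (camera adjusted p = 1.65e-14). Stem cell genes were also negative, where 15 of 19 tested members fell (17 adjusted over the list alone), mean log2 change −0.81 (camera adjusted p = 6.82e-09). For ribosomal protein genes, 4 of 86 tested members rose and 75 fell (4 and 75 adjusted over the list alone), mean log2 change −0.57 (camera adjusted p = 3.98e-28). In these counts a member rose or fell when its day 3 effect lay above or below its day 1 effect. In the proximal regional list, 3 of 6 tested members rose and 2 fell (3 and 2 adjusted over the list alone), mean log2 change −0.014 (camera adjusted p = 0.779), and its median was 0.23. Goblet genes did not pass as a list: 4 of 20 tested members rose and 7 fell (4 and 8 adjusted over the list alone), mean log2 change −0.16 (camera adjusted p = 0.0606). The lowest values were those of Defa36 (−7.36 ± 2.73), Ces1d (−4.74 ± 0.21), Rpl23a-ps3 (−2.57 ± 0.86), Defa-ps7 (−2.54 ± 0.41) and Scgb2b17 (−2.52 ± 0.16). Defa36 (adjusted p = 0.0476), Defa-ps7 and Rpl23a-ps3 (adjusted p = 0.0303) have near-identical relatives and are uncertain.

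The calls of Defa36 and Rpl23a-ps3 were lost without single libraries. For Defa36 the adjusted p was 0.0847, 0.0772 and 0.0724 without Fzd5KO day 1 replicate 1, 2 and 3, 0.105 and 0.104 without Fzd5KO day 3 replicate 1 and 3, 0.0887 and 0.0711 without Ctrl day 1 replicate 1 and 3, and 0.094 and 0.0877 without Ctrl day 3 replicate 1 and 2. For Rpl23a-ps3 it was 0.0517, 0.0504 and 0.0586 without Fzd5KO day 1 replicate 1, 2 and 3, 0.0588 and 0.0533 without Fzd5KO day 3 replicate 1 and 2, 0.0658 and 0.0718 without Ctrl day 1 replicate 2 and 3, and 0.0618 and 0.0665 without Ctrl day 3 replicate 1 and 3. Limma called 6434 genes in the interaction, 3665 higher and 2769 lower. Higher genes made up 57.0% as deposited and 37.7% with rescaling (2552 higher and 4221 lower). Camera called 22 lists, 9 with an estimated correlation, and fry 30.

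From day 1 to day 3 in the control, stem cell and G2 and M phase genes rose and enterocyte, interferon and lymphocyte genes fell. For stem cell genes, 14 of 19 tested members rose (16 adjusted over the list alone), mean log2 change 0.49 (camera adjusted p = 2.78e-06, adjusted p = 0.0657 with an estimated correlation). For G2 and M phase genes in the control, 21 of 26 tested members rose (23 adjusted over the list alone), mean log2 change 0.37 (camera adjusted p = 1.68e-06, adjusted p = 0.0657 with an estimated correlation). For S phase genes, 13 of 26 tested members rose and 1 fell (13 and 1 adjusted over the list alone), mean log2 change 0.24 (camera adjusted p = 0.0117, adjusted p = 0.188 with an estimated correlation). For enterocyte genes, 2 of 27 tested members rose and 24 fell (2 and 24 adjusted over the list alone), mean log2 change −0.57 (camera adjusted p = 1.94e-26, adjusted p = 0.0657 with an estimated correlation). For interferon genes, 1 of 23 tested members rose and 19 fell (2 and 19 adjusted over the list alone), mean log2 change −0.47 (camera adjusted p = 1.13e-12). Of T cell genes, 14 of 15 tested members fell (15 adjusted over the list alone), mean log2 change −1.41 (camera adjusted p = 3.88e-16). Of ribosomal protein genes, 75 of 86 tested members rose and 3 fell (75 and 3 adjusted over the list alone), mean log2 change 0.31 (camera adjusted p = 5.58e-20, adjusted p = 0.0657 with an estimated correlation). Among the largest rises were those of Mcpt1 (2.03 ± 0.10), Ces1d (1.99 ± 0.15), Omp (1.86 ± 0.11) and the fatty acid desaturase Scd1 (1.80 ± 0.090). The largest falls were those of Nr1d1 (−3.69 ± 0.087), Dbp (−3.24 ± 0.087), Mt2 (−2.37 ± 0.13), the chemokine Ccl5 (−2.31 ± 0.16) and Gzma (−2.20 ± 0.070). Limma called 5236 genes, 3633 higher and 1603 lower. Higher genes made up 69.4% as deposited, 49.2% with quantile normalization and 42.3% with median-of-ratios scaling (1835 higher and 2504 lower). Camera called 20 lists, 3 with an estimated correlation, and fry 25.

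In the knockout, Paneth and cell cycle genes fell from day 1 to day 3 while enterocyte, interferon and cholesterol genes rose. For Paneth genes, 17 of 18 tested members fell (17 adjusted over the list alone), mean log2 change −1.58 (camera adjusted p = 1.59e-25). Among S phase genes, 19 of 26 tested members fell (23 adjusted over the list alone), mean log2 change −0.38 (camera adjusted p = 3.36e-12). For stem cell genes, 1 of 19 tested members rose and 12 fell (2 and 13 adjusted over the list alone), mean log2 change −0.33 (camera adjusted p = 1.41e-07). For enterocyte genes, 25 of 27 tested members rose and 2 fell (25 and 2 adjusted over the list alone), mean log2 change 0.64 (camera adjusted p = 9.21e-13, adjusted p = 0.141 with an estimated correlation). Among interferon genes, 23 of 23 tested members rose (23 adjusted over the list alone), mean log2 change 1.33 (camera adjusted p = 9.21e-13). Of cholesterol genes, 19 of 20 tested members rose (19 adjusted over the list alone), mean log2 change 0.65 (camera adjusted p = 1e-08, adjusted p = 0.0535 with an estimated correlation). Of B and plasma cell genes, 10 of 11 tested members rose (10 adjusted over the list alone), mean log2 change 1.64 (camera adjusted p = 1.4e-05, adjusted p = 0.0555 with an estimated correlation). The T cell list did not pass: 5 of 15 tested members rose (5 adjusted over the list alone), mean log2 change 0.22 (camera adjusted p = 0.828). The largest rises were those of Ubd (5.10 ± 0.14), Scd1 (3.45 ± 0.090), Ifi44 (3.10 ± 0.093), Ly6a (2.83 ± 0.13) and Igkv6-15, listed at 0 in Fzd5KO day 1 and at 9.05 ± 3.51 TPM in Fzd5KO day 3. The largest falls were those of the alpha-defensins Defa23 (−3.03 ± 0.16) and Defa30 (−2.26 ± 0.044), the cytochrome P450 gene Cyp2c29 (−2.88 ± 0.063), Ces1d (−2.75 ± 0.15) and AY761184 (−2.22 ± 0.057). Limma called 6510 genes, 4985 higher and 1525 lower. Higher genes made up 76.6% as deposited, 51.6% with quantile normalization, 56.2% with median-of-ratios scaling and 44.1% with rescaling (2711 higher and 3438 lower). Camera called 21 lists, 9 with an estimated correlation, and fry 30.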

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

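All tests of explanations and all counts of other splits in this part were chosen after the results were seen. Genotype effects are compared as the interaction, day 3 minus day 1, on the log2(TPM + 1) scale. It can come mainly from change in Ctrl, as for T cell genes and Nr1d1 above. Limma called 6434 of 14510 tested genes. Of 222 genes named by rule or as list members, 198 differed between the days, 111 above 0 and 87 below, and 24 did not pass. Most of these genes were chosen for a large change or a small p, so a high share was built in. Among the lists, camera called 22, of which 9 held with an estimated correlation. Mean interactions lay above 0 for MHC class II presentation (1.82), interferon response (1.80), B and plasma cell (1.75), T cell and intraepithelial lymphocyte (1.63), enterocyte (1.21), fetal-like and regenerative (1.10), myeloid (1.001), distal intestine regional (0.82), cholesterol biosynthesis (0.70), glycolysis (0.42) and unfolded protein and integrated stress response (0.41). With an estimated correlation calls were lost for B and plasma cell, fetal-like and regenerative and cholesterol biosynthesis (adjusted p = 0.0517), T cell and intraepithelial lymphocyte and glycolysis (p = 0.0791), enterocyte and myeloid (p = 0.0717), distal intestine regional (p = 0.07) and unfolded protein and integrated stress response (p = 0.112). Means lay below 0 for Paneth cell (−1.29), tuft cell (−0.98), erythroid (−0.86), intestinal stem cell (−0.81), enteroendocrine cell (−0.76) and cell cycle G2 and M phase (−0.67). They were also below 0 for cell cycle S phase (−0.62), ribosomal protein (−0.57), Wnt beta-catenin target (−0.41), mitochondrially encoded (−0.37) and Notch pathway (−0.33). With an estimated correlation calls were lost for erythroid and mitochondrially encoded (adjusted p = 0.191), Wnt beta-catenin target (p = 0.131) and Notch pathway (p = 0.151).

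A gene of several lists is given under 1 of them. Intestinal stem cell members were Clca3b (−0.52), Igfbp4 (−0.69), Myb (−1.11), Slc12a2 (−1.14), Ascl2 (−1.28), Olfm4 (−1.52) and Gkn3 (−1.63). Wnt beta-catenin target members were Axin2 (−0.81). Wnt receptor members were Fzd7 (0.35), Fzd1 (−0.61) and Ror2 (−0.68). Cell cycle S phase members were Slbp (−0.26), Uhrf1 (−0.58), Mcm6 (−0.67), Mcm7 (−0.87), Mcm5 (−0.88), Prim1 (−1.0) and Tyms (−1.02). Cell cycle G2 and M phase members were Mki67 (−0.66), Top2a (−0.74), Kif11 (−0.78) and Ccna2 (−0.83). Paneth cell members were Defa22 (−0.99), Ang4 (−1.10), Lyz1 (−1.17), Defa17 (−1.65), Defa24 (−1.75), Defa30 (−2.06), Clps (−2.06) and Defa23 (−2.21). Goblet cell members were Clca1 (0.72), Muc2 (0.52), Zg16 (0.17), Tff3 (−0.44), Spink4 (−0.84) and Ccl6 (−1.07). Enteroendocrine cell members were Reg4 (−0.67), Cck (−0.81), Gcg (−1.05), Chgb (−1.36), Gip (−1.45), Chga (−1.51) and Ghrl (−1.57). Tuft cell members were Pou2f3 (−0.74), Trpm5 (−1.24), Rgs13 (−1.36) and Dclk1 (−2.34). Enterocyte members were Slc15a1 (2.17), Slc2a2 (2.12), Sis (1.91), Slc5a1 (1.90), Alpi (1.21), Apoa4 (0.74), Fabp1 (0.70), Lct (0.22) and Cubn (0.20). Antimicrobial and mucosal defence members were Duoxa2 (1.40), Duox2 (1.03), Il18 (0.28), Reg3b (0.26), Ccl28 (−1.06) and Reg3a (−1.12). Fetal-like and regenerative members were Ly6a (3.22), Areg (2.52), Il33 (2.17), Ereg (1.49), S100a6 (1.18) and Clu (0.63). P53 target members were Cdkn1a (0.91), Sesn1 (0.80), Apaf1 (0.65) and Perp (0.36). Notch pathway members were Dll4 (0.78), Dtx4 (−0.65), Lfng (−0.78), Notch1 (−0.88) and Nrarp (−0.89). BMP and TGF-beta target members were Bmp2 (1.69), Bmpr1a (0.57), Smad6 (−0.63) and Bmp7 (−0.78). Unfolded protein and integrated stress response members were Trib3 (2.04), Dnajb9 (1.04), Creld2 (0.50), Hspa5 (0.47), Xbp1 (0.29), Pdia4 (0.25) and Pdia6 (0.14). Interferon response members were Ifi44 (3.88), Oas1a (2.48), Oasl2 (2.16), Zbp1 (1.91), Tap1 (1.74), Ifit3 (1.53) and Irf1 (0.44). MHC class II presentation members were H2-Aa (2.61), H2-Ab1 (2.39), Cd74 (2.21) and H2-Eb1 (2.16). Cholesterol biosynthesis members were Msmo1 (1.22), Insig1 (1.06), Sqle (0.99), Hmgcs1 (0.97), Stard4 (0.69) and Dhcr7 (0.50). Fatty acid oxidation and ketogenesis members were Acadl (1.19), Creb3l3 (0.88), Ehhadh (0.80), Cpt1a (0.30) and Slc25a20 (0.18). Glycolysis members were Pkm (0.76), Eno1 (0.75), Ldha (0.64) and Pfkp (0.51). Proximal intestine regional members were Slc39a4 (0.61), Gata4 (0.24) and Onecut2 (−0.75). Distal intestine regional members were Fabp6 (1.93), Slc51a (1.55), Slc10a2 (1.51), Slc51b (1.40) and Fgf15 (−0.43). Circadian clock members were Nr1d1 (4.18), Dbp (2.91), Nr1d2 (2.40) and Clock (0.20). Immediate early and dissociation stress members were Socs3 (1.83), Klf6 (1.05), Zfp36 (1.005), Fos (0.84), Jun (0.55) and Hspa1b (−1.05). T cell and intraepithelial lymphocyte members were Ccl5 (2.89), Gzma (2.74), Gzmb (2.23), Cd7 (1.86), Cd3g (1.84) and Itgae (1.60). B and plasma cell members were Igha (2.73), Igkc (2.58), Ighm (2.46) and Jchain (1.77). Myeloid members were Csf1r (1.65), C1qa (1.55), Lyz2 (1.37), C1qb (1.28) and Mrc1 (1.13). Fibroblast and smooth muscle members were Bgn (0.94) and Dcn (0.55). Endothelial members were Pecam1 (0.68), Lyve1 (0.60) and Egfl7 (−0.68). Erythroid members were Hba-a2 (−0.69), Hbb-bt (−1.01), Hba-a1 (−1.12) and Hbb-bs (−1.14). Ribosomal protein members were Rps6ka5 (0.50), Rpl4 (−0.68), Rpl8 (−0.71), Rps3a1 (−0.74), Rpl3 (−0.79), Rps12 (−0.79), Rpl32 (−0.86) and Rpl36 (−0.91). Mitochondrially encoded members were mt-Nd5 (−0.26), mt-Rnr2 (−0.38), mt-Nd4 (−0.58), mt-Cytb (−0.71) and mt-Nd2 (−0.72). Enteric neuron and glia members were Ret (0.43). Genes named for their size were Ubd (5.90), Igkv6-15 (3.25), Sprr2a3 (2.86), Sprr2a2 (2.698), Ada (2.53), Mt2 (1.84), Scd1 (1.65), Rims2 (1.63), Slc28a2 (1.02), Nt5e (0.86), Mt1 (0.76), Mettl21a (0.36), Fzd5 (−0.24) and Paqr7 (−0.28). Others of these were Mcpt1 (−0.39), Msi1 (−0.66), Sorbs2 (−1.44), Omp (−1.46), Afp (−1.55), Cyp2c29 (−1.56), Cdo1 (−1.59), AY761184 (−2.06), Reg1 (−2.44), Scgb2b17 (−2.52), Defa-ps7 (−2.54), Rpl23a-ps3 (−2.57), Ces1d (−4.74) and Defa36 (−7.36). Igkv6-15 was listed at 0 in Fzd5KO day 1, so its value depends on the pseudocount, and single Defa, Sprr2a and Rpl23a-ps3 values are uncertain because of near-identical copies.

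For 3 libraries against 3 only 10 splits exist, too few for a share under 0.05. The real split gave 3622 genes at day 1 and the highest other 2 (lists: 16 and 6). At day 3 these were 9113 and 2 (lists: 28 and 24). Time in control gave 5236 against 4 and in knockout 6510 against 2. For the mean of both days 1 of 100 splits within days, the real one, reached 8543 genes. The highest other (6502) kept the day 3 groups. For the interaction 5 of 100 splits reached 6434 genes and the highest other gave 8543. All 4 others as large exchanged all 3 Ctrl day 3 libraries with the knockout ones, which turns the interaction towards the mean effect. Neither count therefore tests chance, and replicates may be technical. Splits that mixed the day 3 libraries called at most 12 genes.

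Mettl21a and 2810408I11Rik, beside Fzd5 on its strand, rose on both days. Scaling of the TPM values is argued against, because the smallest rise of the pair over the scalings that keep the gene was 3.39. A local effect of the changed allele or of its flanking segment stays open, since 0 of the other 9 tested genes within 1 Mb changed by more than 1 in the same direction on both days (Fisher's exact two-sided p = 1), which does not exclude an effect on the pair alone. Transcription running on past Fzd5 stays open too: 2 of 3 downstream genes on its strand and 0 of 3 on the other rose (Fisher's exact two-sided p = 0.4), and the smallest p that 3 genes against 3 allow is 0.1. A changed allele and a strain difference beside it cannot be told apart here.

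Clock genes of Ctrl day 3 stood apart from the other 3 groups. Scaling as the whole cause is argued against, because it moves all genes of a library the same way, while the medians of the 2 sides of the clock moved in opposite directions, by at least 0.922 over the scalings. Loss of Fzd5 stays open: the sides moved apart by 0.346 in Fzd5KO against Ctrl at day 1, which does not exclude that it blocks a change over time seen in the control. Another phase of the daily clock or of feeding in Ctrl day 3 stays open as a hypothesis, since collection times are not given in the sources used here. Without Nr1d1, Dbp and Arntl the sides moved apart by 1.89 between the control groups, in 14 genes of a list already seen to differ, which decides nothing.

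Interferon genes rose in Fzd5KO day 3. Low values in Ctrl day 3 as the whole cause are argued against, because the list mean was 1.11 against Ctrl day 1 and stayed called. Against Ctrl day 1 more T cells and intraepithelial lymphocytes are argued against (list mean −0.0822), but against Ctrl day 3 they stay open (1.32). More B, plasma and myeloid cells could contribute and cannot be told apart from an epithelial response. Their lists rose by 1.22 (B and plasma) and 0.69 over Ctrl day 1. An effect of the genotype stays open and was not tested apart from these.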

How the results depend on the processing

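The comparison of day 3 calls with Ctrl day 1 was chosen after the data were seen, and all other settings before. Of results not leaving out a library, 3194 gene results kept direction and call, 105 lost the call, 5 gained one and 9 reversed. For lists these were 750, 44, 36 and 20, and of main values 153 stayed and 12 moved. With a library left out, 3535 gene results were the same, 119 lost the call, 2 gained one and 4 reversed. For lists these were 773, 4, 12 and 3, and of main values 167 stayed and 1 moved. Genes called at day 1 (3622) became 1771 with quantile normalization, 2216 with median-of-ratios scaling, 1925 with rescaling and 71 with a change of at least 1. Day 3 calls (9113) became 1264 with a change of at least 1 and 5933 when also required against Ctrl day 1. Camera with an estimated correlation called 1 list at day 1 (main 16), 13 at day 3 (28), 13 for the mean of days (27), 9 for the interaction (22), 3 for time in control (20) and 9 for time in knockout (21). Leaving out 1 library gave 2229 (without Ctrl day 1 replicate 2) to 3674 genes at day 1, 8382 to 9124 at day 3, 8060.0 to 8463 for the mean, 5961 to 6207 for the interaction, 4142 to 5220.0 for time in control and 5777 to 6530.0 for time in knockout. Lists ranged from 15 to 19 at day 1, 28 at day 3, 27 for the mean, 22 to 25, 20 to 21 and 21 to 22. The Fzd5 change ranged from −0.54 to −0.45 at day 1 and −0.78 to −0.70 at day 3.

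Day 1 reversals follow, and the cause was not tested. With quantile normalization they were Dclk1 (0.12), Lyve1 (0.060), the unfolded protein list (0.014) and the cholesterol list (0.021). With median-of-ratios scaling they were Alpi (0.14), Dclk1 (0.11), Hmgcs1 (0.037), Pdia4 (0.0050), Sesn1 (0.017), and the lists of enterocyte (0.036), unfolded protein (0.055), cholesterol (0.065), myeloid (−0.00097) and endothelial genes (−0.060). With rescaling they were Alpi (0.068), Dclk1 (0.055), and the unfolded protein (−0.013), cholesterol (−0.0024) and endothelial lists (−0.13). Without a filter the distal (0.027), circadian (−0.10) and endothelial lists (−0.078) turned against the other genes, and without a trend the unfolded protein list (−0.11). Fry gave the opposite direction for fetal-like (−0.026), circadian (−0.11), myeloid (−0.10) and endothelial genes (−0.15). Values for a reversed list are its mean, which can keep its sign.

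Leaving out 1 library, Dclk1 ranged from −0.14 to 0.045 (without Ctrl day 1 replicate 2), and was 0.0079 and 0.0090 without Fzd5KO day 1 replicate 1 and 2. Lyve1 ranged from −0.22 to 0.013 (without Ctrl day 1 replicate 2). The tuft list ranged from −0.29 to −0.23 and turned against the other genes without Ctrl day 1 replicate 1 (−0.24). Without Fzd5KO day 1 replicate 3 the unfolded protein (−0.10, range −0.13 to −0.094) and endothelial lists (−0.22) turned. At day 3 median-of-ratios scaling turned the proximal (−0.041) and endothelial lists (−0.075).

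With the replicate number as a block, limma called 3414 genes at day 1, 9029 at day 3, 8473 for the mean, 6349 for the interaction, 5102 for time in control and 6394 for time in knockout, and at day 1 the Wnt target list was lost (adjusted p = 0.0666) and the erythroid list called (0.0447). The labels share only a number: over 18 same-number pairs r ran from −0.0692 to 0.0926, 0 over 0.1, and 7 of 12 libraries correlated best with their own number. A fit of only the compared groups was not run for the mean and the interaction, which use all 4. Depth was unknown, so its limits could not be given.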

Other observations

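The comparison with Ctrl day 1 in this part was chosen after the data were seen, the lists and other contrasts before, and no explanation was tested. Glycolysis genes were higher at day 3. In that list, 12 of 15 tested members rose (13 adjusted over the list alone), mean log2 change 0.49 (camera adjusted p = 3.32e-07), and 0.57 against Ctrl day 1, with Pkm, a pyruvate kinase, at 0.79 and Eno1, an enolase, at 0.91. At day 1, 8 of 15 tested members rose and 2 fell (8 and 2 adjusted over the list alone), mean log2 change 0.073 (camera adjusted p = 4.34e-08, adjusted p = 0.0796 with an estimated correlation). In the list of fatty acid oxidation and ketogenesis, 11 of 20 tested members rose and 5 fell (11 and 5 adjusted over the list alone), mean log2 change 0.20 (camera adjusted p = 0.0071, adjusted p = 0.0945 with an estimated correlation) at day 3, a call lost with quantile normalization (0.0544), with Acadl at 1.83, and 0.56 against Ctrl day 1. At day 1 of this list, 4 of 20 tested members rose and 5 fell (4 and 6 adjusted over the list alone), mean log2 change 0.028 (camera adjusted p = 0.00489, adjusted p = 0.188 with an estimated correlation).

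Genes of the distal intestine rose at day 3. In the distal list, 6 of 9 tested members rose (6 adjusted over the list alone), mean log2 change 0.85 (camera adjusted p = 0.000585), and 0.56 against Ctrl day 1. Fabp6, a bile acid carrier of the ileum, was at 146 ± 0.442 TPM in Ctrl and 466 ± 14.03 TPM in Fzd5KO, and the bile acid transporter Slc10a2 at 1.81 ± 0.0611 and 6.05 ± 0.553 TPM. At day 1 of the distal list, 1 of 9 tested members rose and 2 fell (1 and 2 adjusted over the list alone), mean log2 change 0.027 (camera adjusted p = 0.675), with a median of −0.12. In the proximal list, 1 of 6 tested members rose and 2 fell (1 and 2 adjusted over the list alone), mean log2 change −0.18 (camera adjusted p = 0.736) at day 3, but 0.092 against Ctrl day 1. At day 1 in this list 2 of 6 tested members fell (1 rose and 3 fell adjusted over the list alone), mean log2 change −0.17 (camera adjusted p = 0.661).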
